A study of Mus musculus with 16 samples.

How the data were processed

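Small RNA libraries of 16 samples were analysed: 12 of RAW264.7 cells, in 4 groups of 3, and 4 of EV preparations, 1 each. Per the labels' protocols, EVs were collected by ultracentrifugation, a plant miRNA was added to EV RNA before extraction, libraries were made with the NEBNext small RNA kit and sequenced on a MiSeq as single reads of 51 bp. No entry for the plant miRNA is in the tables analysed. The dose of Con A given to the recipient cells is not given in the sources used here. Groups were taken from the sample titles, and 0 columns of the tables matched no sample.

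The authors deposited raw counts as whole reads per mature mouse miRNA name, with 941 names each for cells and EVs, of which 781 and 649 had reads. The aligner, the miRNA annotation and the genome build are not given in the sources used here. The authors also deposited normalized signal values in 5 of the 7 tables. In the 3 tables of cells each deposited signal value was the raw count times 1 factor per library, and miRNAs with a total of 10 reads or fewer were left out, as tested on the values. In the 2 EV tables each deposited signal value was the raw count divided by 1 whole number per library, with miRNAs at 0 in either library left out. These divisors were 126 for serum saline, 2 for serum Con A, 13 for RAW saline and 16 for RAW Con A EVs, and what they count is not stated. edgeR is named, without a version, per the submitters' processing notes.

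Cell libraries were tested in R 4.3.3 with edgeR 4.0.16. Raw counts were filtered by filterByExpr, which kept 229 miRNAs, and scaled by TMM, and 1 quasi-likelihood model was fitted to all 12 libraries. Tests were 2-sided, with Benjamini-Hochberg adjustment within each of 5 comparisons and a threshold of 0.05. Levels are TMM-scaled CPM with the SD of 3 libraries, and fold changes are log2 with the fit's standard error. miRNAs at 0 reads in a group have a lower bound computed with 3 reads over the group. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside an estimated correlation and fry, with adjustment over the 12 lists with at least 3 tested members per comparison, 60 tests in all. Shared directions were set beside 100 simulated draws of unchanged groups against the same PBS libraries. Comparisons, tests, lists, alternatives and the naming rule were fixed before the data were examined, and additions are named as such in the closing section.

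EVs were compared by CPM of miRNA reads, with exact 95% intervals for the ratio of 2 Poisson counts and Wilson intervals for shares, among miRNAs with at least 50 reads over both libraries. No p-values are given for EVs. The median ratio of a list was placed among 10000 random lists matched on abundance, each member drawn from 20 neighbours in rank. Members that share a transcript, a hairpin or a sequence were counted separately, so percentiles of such lists may be too extreme. EV miRNA lists tested in cells were the 30 most abundant miRNAs of each EV preparation given to cells, and the miRNAs with at least 100 CPM in serum Con A EVs and at least 8 times their CPM in both RAW EV libraries.

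The miRNAs named in a cell comparison were, among calls with a mean of at least 10 CPM, the 12 largest rises and 12 largest falls, 2 to 4 members of each list with the smallest p, and a fixed panel (miR-155-5p, miR-146a-5p, miR-21a-5p, miR-142a-3p, miR-223-3p, miR-122-5p, miR-451a and miR-126a-3p). In EVs they were the 12 highest and 12 lowest ratios with an interval that excludes 1, that panel, and the 10 most abundant miRNAs of each library. Names outside this rule were chosen after their values were seen: in cells the remaining members of the chromosome X cluster, miR-22-3p in cells given serum Con A EVs, and the miRNAs of the EV lists.

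The 20 fixed lists, with members and members tested in cells, were inflammation-induced macrophage miRNAs (12, 7), the miR-99b/let-7e/miR-125a cluster and relatives (8, 8), myeloid miRNAs (8, 4), the let-7 family (9, 9), the Mir17hg cluster and paralogous clusters (14, 11), miR-30 (7, 7), miR-29 (4, 3), miR-15/16 (6, 5), the miR-23/27/24 clusters (7, 7), the miR-221 and miR-222 cluster (4, 4), miR-181 (4, 2), the Sfmbt2 cluster (28, 0), erythrocyte (7, 1), hepatocyte (6, 3), endothelial and platelet (4, 2), lymphocyte (4, 1), muscle (8, 0), epithelial and islet (8, 2) and stromal and vascular smooth muscle miRNAs (7, 3), and the Dlk1-Dio3 imprinted cluster (18, 0). The lymphocyte and miR-181 lists share members, and let-7e-5p is in both the let-7 and the miR-99b lists, so its calls count in both. Locus relations came from a RefSeq gene table of GRCm38.p6, and no coordinates are given because the authors' build is unknown.

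Cell libraries held 174510 to 403332 miRNA reads and EV libraries 114791 to 334285. In simulated data with 200 changed miRNAs and 10 draws, the cell test recovered 90.2% of miRNAs changed 2-fold and 40.4% of those changed 1.25-fold in serum Con A EVs against PBS, and 3.97% of its calls were false. For RAW Con A EVs against PBS these were 81.5%, 45.7% and 4.57%, for RAW saline EVs against PBS 83.5%, 37.3% and 4.57%, for RAW Con A against RAW saline EVs 83.1%, 51.2% and 3.90%, and for serum Con A against RAW Con A EVs 88.1%, 41.9% and 4.77%. At an unadjusted camera p under 0.05, the list test called 20 of 20 shifted and 1 of 20 unchanged simulated lists. All members of a shifted list moved by the same factor in the same direction, so power for smaller or mixed changes is not shown. Simulated miRNAs were drawn independently of each other, so the rate of false calls for lists with correlated members is not shown either. In the real lists the estimated correlation reached 0.604 (stromal miRNAs, serum Con A EVs against PBS). The ratio interval covered the true value in 94.9 to 98.55% of 2000 simulated pairs. Replicate libraries differed by more than counting error, with a chi-square per degree of freedom of 1.84 to 8.30.

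Alternatives were DESeq2 size factors, upper-quartile scaling and library size alone in edgeR, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the authors' deposited values with a pseudocount of 1, no filter, a filter of 10 CPM in 3 libraries, a fit to the 2 groups alone, a replicate block, and leaving out each library in turn. For EVs they were TMM, the authors' deposited values, minimums of 20 or 200 reads and a ratio of 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads themselves, other RNA classes, cytokine measurements and targets of miRNAs were not analysed here.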

Results

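MicroRNAs (miRNAs) were sequenced from cultured mouse macrophages and from extracellular vesicles (EVs), the membrane-enclosed particles that cells shed. The recipient cells were RAW264.7, a mouse macrophage line derived from a virus-induced tumour. They received PBS or EVs at 6e9 particles per mL for 8 h in EV-free medium and then concanavalin A (Con A) for 16 h. Con A is a plant lectin that activates T cells and causes hepatitis when injected into mice. The 4 groups of cells, with 3 libraries each, had received PBS, EVs from serum of mice injected with Con A (serum Con A EVs), EVs from RAW264.7 cells cultured with Con A (RAW Con A EVs) or EVs from RAW264.7 cells cultured with saline (RAW saline EVs). No cells received EVs from serum of saline-injected mice. Effects of serum Con A EVs therefore cannot be told apart from effects of serum EVs as such. The comparison of serum Con A with RAW Con A EVs also differs in the source of the EVs. The EVs themselves gave 4 libraries. Serum EVs came from BALB/c mice 9 h after saline or Con A at 15 mg/kg, and RAW EVs came from medium after 24 h with saline or Con A at 25 µg/mL. The series title asks about macrophage EVs in Con A hepatitis and the production of cytokines by macrophages, and the miRNA tables bear on what the EVs carry and on what changes in cells that receive them.

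The PBS libraries held 222375, 302162 and 308824 miRNA reads, and those of cells given serum Con A EVs 347877, 276323 and 285968. Cells given RAW Con A EVs gave 174510, 244954 and 403332 reads, and cells given RAW saline EVs 227745, 364910 and 240248. The EV libraries held 132130 reads for serum saline, 334285 for serum Con A, 114791 for RAW saline and 134884 for RAW Con A. A count of 0 allows a level of up to 7.44 to 17.2 CPM (reads of a miRNA scaled to the miRNA total of its library) in a cell library. In the EV libraries it allows up to 22.7, 8.97, 26.1 and 22.2 CPM, in the order above. Intervals and floors cover counting error only. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. In every cell library the most abundant miRNA was miR-21a-5p, a miRNA common in macrophages, with 24.0 to 28.6% of the reads. Scaling by library size alone in place of TMM would shift the median log2 change of all tested miRNAs by −0.14 in cells given RAW Con A EVs, by −0.10 in cells given RAW saline EVs, and by 0.22 between cells given serum Con A EVs and RAW Con A EVs. No call that an alternative shared with the main test had the opposite sign (0 in each of the 5 cell comparisons).

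In cells given serum Con A EVs, miR-155-5p, which inflammatory signals induce in macrophages, fell to 217 ± 13.8 CPM from 1038 ± 112 CPM in PBS cells (mean ± SD, n = 3 and 3), a 4.78-fold lower level. Its hairpin partner miR-155-3p fell from 177 ± 43.3 to 41.5 ± 12.0 CPM. miR-192-5p and miR-194-5p, which are abundant in liver and gut, fell from 935 ± 146 to 237 ± 8.03 CPM and from 241 ± 51.5 to 63.9 ± 10.8 CPM. They share a transcript from chromosome 19, but miR-194-5p also has a gene on chromosome 1. Among the miRNAs that rose was miR-122-5p, the main miRNA of hepatocytes, from 18.8 ± 8.87 to 196 ± 46.2 CPM. miR-148a-3p, also abundant in liver, rose from 17.6 ± 8.24 to 282 ± 58.7 CPM. miR-451a, an erythrocyte miRNA, went from 0 reads over the PBS libraries to 67 reads, at least 20.4-fold higher with a floor of 3 reads over the group. Adjusted p by edgeR's quasi-likelihood test was 2.54e-18 for miR-155-5p, 2.70e-12 for miR-148a-3p, 3.21e-12 for miR-192-5p and 6.99e-11 for miR-122-5p. It was 1.13e-08 for miR-155-3p, miR-194-5p and miR-451a. Each of these lay beyond all PBS libraries in 3 of 3 libraries and kept its call without any 1 of the 6 libraries.

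miRNAs of a cluster on chromosome X (the genes Mir322, Mir503, Mir351, Mir542 and Mir450, which lie within 6258 bp in GRCm38.p6) also fell in cells given serum Con A EVs. This cluster was no fixed list and was chosen after its values were seen. Of its 8 tested members 6 fell, with log2 changes of −1.88 for miR-450b-5p (SE 0.21, adjusted p = 1.13e-08 by edgeR's test), −1.30 for miR-450a-5p, −1.22 for miR-503-5p, −1.14 for miR-542-3p, −0.88 for miR-322-3p and −0.76 for miR-351-5p. The other members, miR-322-5p at −0.42 and miR-503-3p at −0.47, had adjusted p of 0.186 and 0.303. miR-222-3p, which represses the cell cycle inhibitor p27, fell from 5320 ± 728 to 2756 ± 156 CPM (adjusted p = 2.17e-11). miR-22-5p and miR-22-3p fell by 1.34 and 0.71 on the log2 scale, and miR-671-5p by 0.90. Smaller rises were those of miR-130b-5p, from 1218 ± 162 to 1709 ± 135 CPM (adjusted p = 1.82e-05), and of the endothelial miR-126a-3p, from 592 ± 18.8 to 770 ± 26.5 CPM (adjusted p = 0.00271). let-7c-2-3p, let-7a-1-3p and miR-339-5p rose by 0.49, 0.46 and 0.35. Every call named here was beyond all PBS libraries in 3 of 3 libraries and kept its call without any 1 library.

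Of 229 tested miRNAs, 49 passed in cells given serum Con A EVs, 18 higher and 31 lower, of which 4 and 9 by at least 2-fold. The groups did not overlap for 83 miRNAs, or 36.2%, where chance gives 10% at 3 against 3. With upper-quartile scaling the split was 13 higher and 37 lower, with library size alone 33 and 21, and with limma-trend 12 and 34. Of the 49 calls, 29 held without any 1 library. The other calls ended in at least 1 such fit, at log2 changes of the same sign that were 0.627 to 1.13 times the full value. Those of miR-301b-5p (log2 change 1.25), miR-106b-3p (0.33) and miR-125b-5p (−0.22) ended without PBS library 3 (adjusted p = 0.0566, 0.0543 and 0.0577), and that of miR-20a-5p (0.19) without PBS library 2 (0.0734). miR-92a-1-5p (0.89) was not called without PBS library 3 or serum Con A EV library 1 (0.0847 and 0.135), and miR-222-5p (−0.74) without PBS library 1 or serum Con A EV library 1 (0.0753 and 0.141). miR-21a-5p (−0.18) and miR-23b-3p (−0.33, lower in 2 of 3 libraries) lost their calls without PBS library 2, PBS library 3 or serum Con A EV library 1 (highest adjusted p = 0.154 and 0.102). miR-25-3p (0.18) lost it without these or serum Con A EV library 2 (up to 0.294), and miR-338-5p (0.85) without any library but PBS library 1 (up to 0.204). The call of miR-106b-5p (0.29) ended without any library but serum Con A EV library 1 (up to 0.228), and that of let-7c-5p (−0.16) without any of the 6 (0.0567 to 0.179). miR-146a-5p, a brake on NF-κB signalling, stood at a log2 change of 0.11 (adjusted p = 0.270), the granulocyte miRNA miR-223-3p at 0.01 (0.997) and the blood cell miRNA miR-142a-3p at −0.04 (0.750).

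By lists fixed before the data were examined, the miR-221 and miR-222 cluster was lower as a whole in cells given serum Con A EVs (median log2 change −0.66, camera adjusted p = 1.10e-04, and adjusted p = 0.0482 with an estimated correlation). All 4 members fell, 4 also adjusted over the list alone, among them miR-221-3p (−0.58) and miR-221-5p (−0.59). Inflammation-induced macrophage miRNAs were lower (camera adjusted p = 0.0417, and adjusted p = 0.123 with an estimated correlation). Of 7 tested, 1 rose (miR-9-5p, 0.26) and 3 fell (miR-155-5p, miR-155-3p and miR-21a-5p), 1 and 3 adjusted over the list alone, and the median was −0.12 with a mean of −0.61. miR-21a-5p here lost its call without PBS library 2, PBS library 3 or serum Con A EV library 1 (0.101, 0.0924 and 0.154). Of the 11 tested miRNAs of the Mir17hg cluster and its paralogues, which promote cell growth, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.18 and camera adjusted p = 0.0523. They included miR-17-5p at 0.24. Of the miR-23/27/24 clusters 2 of 7 fell (3 adjusted over the list alone), miR-27b-3p at −0.24 among them, of the let-7 family 1 of 9 fell (0 adjusted over the list alone) and of the miR-99b cluster and relatives 1 of 8 (1). Of the 3 tested hepatocyte miRNAs 1 rose and 2 fell, the same adjusted over the list alone, with a median of −1.91, a mean of −0.21 and camera adjusted p = 0.220. Myeloid, miR-30, miR-29, miR-15/16 and stromal miRNAs had 0 calls. For 2 of 12 lists the sign of the test, median and mean differed: let-7 (up by camera, median −0.01) and miR-15/16 (up, median 0.07, mean −0.12). The lists that did not pass had camera adjusted p of 0.0523 to 0.957.

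**Figure D1:**
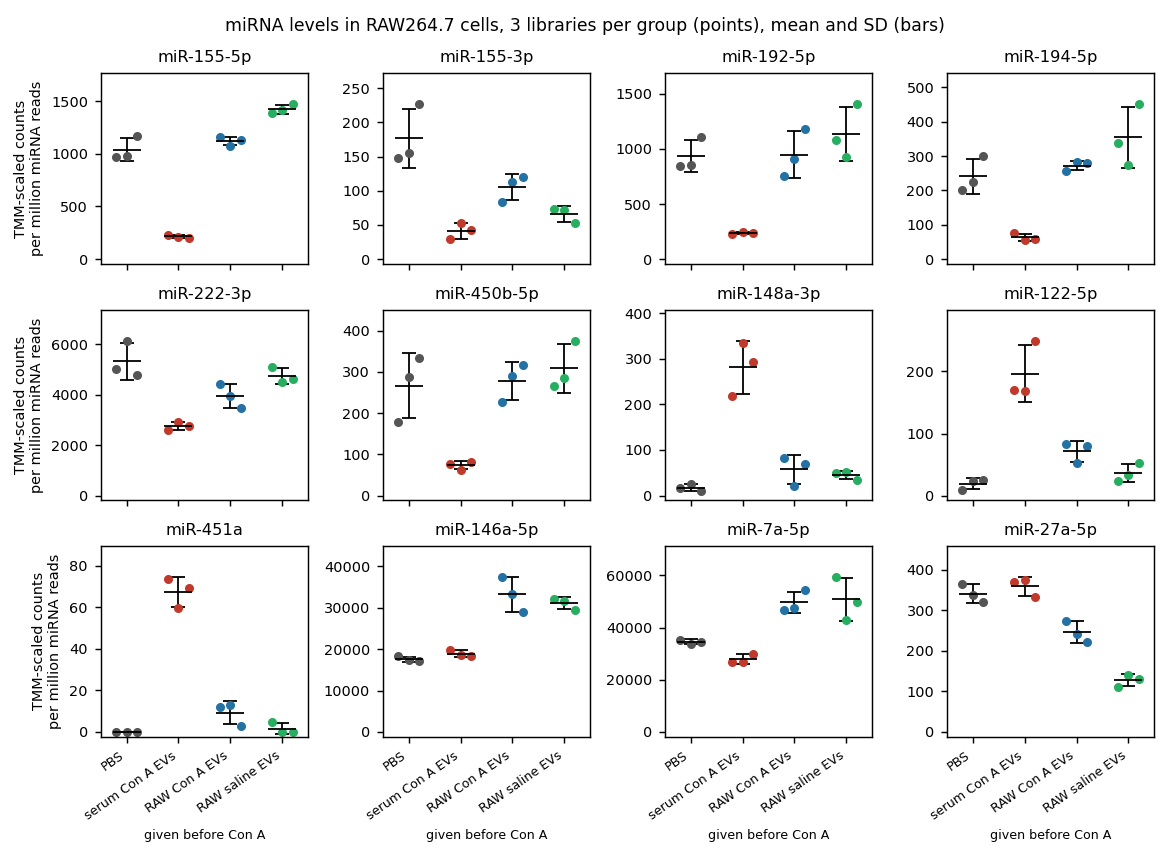
TMM-scaled CPM (linear axes) of 12 miRNAs in each of the 12 cell libraries, with group mean and SD as bars, for cells given PBS, serum Con A EVs, RAW Con A EVs or RAW saline EVs. miR-155-5p averages 217 CPM with serum Con A EVs and 1038, 1121 and 1424 CPM in the other groups.

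In cells given RAW Con A EVs, miR-146a-5p rose from 17565 ± 622 to 33261 ± 4185 CPM, 1.89-fold, and was higher than all PBS libraries in 3 of 3 libraries (edgeR's test, adjusted p = 1.27e-12). miR-7a-5p and miR-7b-5p, whose near-identical sequences may share reads, rose by 0.52 and 0.54 on the log2 scale (SE 0.08 and 0.07, adjusted p = 7.35e-06 and 2.03e-06). The hepatocyte miR-122-5p rose 3.56-fold, from 18.8 ± 8.87 to 71.5 ± 17.1 CPM (adjusted p = 0.00161). miR-221-5p fell from 764 ± 113 to 469 ± 35.1 CPM (adjusted p = 2.38e-05) and miR-222-3p by 0.44 (SE 0.08, adjusted p = 2.45e-04). let-7c-1-3p, the rarer strand of a let-7c hairpin, fell from 191 ± 19.1 to 109 ± 19.4 CPM (adjusted p = 0.00773). These 7 lay beyond all PBS libraries in 3 of 3 libraries and kept their calls without any 1 library. miR-155-5p stood at 1121 ± 40.4 CPM, a log2 change of 0.10 (adjusted p = 0.520), miR-223-3p at −0.66 (0.470) and miR-126a-3p at 0.06 (0.815). In all, 26 miRNAs passed, 14 higher and 12 lower, 3 and 0 of them by at least 2-fold. The groups did not overlap for 58, or 25.3%. The split was 8 and 13 with upper-quartile scaling, 6 and 30 with library size alone, 13 and 7 with DESeq2, and 7 and 9 with no filter.

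The other 19 calls in cells given RAW Con A EVs each ended without at least 1 library, at log2 changes of the same sign that were 0.626 to 1.21 times the full value. Without PBS libraries 1, 2 and 3 in turn, 15, 13 and 14 miRNAs passed, and without RAW Con A EV libraries 1, 2 and 3, 18, 13 and 11 (edgeR). The fall of miR-328-3p (−0.49) ended without RAW Con A EV library 3 (adjusted p = 0.0584), and that of miR-484 (−0.28) without PBS library 3 (0.0741). The rises of miR-3535 (0.48) and miR-5099 (0.42) ended without PBS library 3 (0.0637 and 0.0942) or RAW Con A EV library 3 (0.0813 and 0.146). The rise of miR-148a-3p (1.69, from 17.6 ± 8.24 to 57.8 ± 32.2 CPM, higher in 2 of 3 libraries) ended without PBS library 3 (0.0975), RAW Con A EV library 1 (0.0607) or RAW Con A EV library 3 (0.184). The rise of let-7f-5p (0.22) ended without PBS libraries 2 or 3 or RAW Con A EV library 3 (up to 0.0647). The fall of miR-142a-3p (−0.23) ended without these or RAW Con A EV library 2 (up to 0.217). The fall of miR-155-3p (−0.71, to 105 ± 19.3 CPM) ended without PBS library 3 or any RAW Con A EV library (up to 0.222). miR-19b-3p (0.25) and miR-27a-5p (−0.50) lost their calls without PBS libraries 1 or 2 or RAW Con A EV libraries 2 or 3 (up to 0.144 and 0.150). miR-26a-5p (−0.18) lost its call without PBS libraries 1 or 2 or RAW Con A EV libraries 1 or 2 (up to 0.249). miR-23a-3p (0.28) and miR-339-5p (−0.31) lost theirs without any library but PBS library 3 (up to 0.213 and 0.130), and miR-21a-5p and miR-27a-3p (both 0.19) without any but RAW Con A EV library 1 (up to 0.140 and 0.194). miR-27b-5p (−0.58, lower in 2 of 3 libraries) and miR-451a (6 reads against 0, at least 2.03-fold higher) were not called without any library but RAW Con A EV library 3 (up to 0.240 and 0.167). let-7j (0.22) and miR-222-5p (−0.75) were not called without any 1 of the 6 (up to 0.150 and 0.195).

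The miR-221 and miR-222 cluster was the 1 list that passed in cells given RAW Con A EVs (camera adjusted p = 0.0026, and adjusted p = 0.176 with an estimated correlation). Of its 4 members 3 fell, 3 also adjusted over the list alone, with a median of −0.57. The fall of miR-222-5p, which is 1 of these, ended without any 1 of the 6 libraries (0.0540 to 0.195). Of the inflammation-induced miRNAs 2 rose and 1 fell (the same adjusted over the list alone), with camera adjusted p = 0.138, up by the test and mean (0.06) at a median of −0.003. miR-15/16 members were up by the test at a median of −0.17 and a mean of −0.05, the other of 2 lists whose signs differed, with 0 calls and 1 rise adjusted over the list alone. The miR-23/27/24 clusters had 2 rises and 1 fall (camera adjusted p = 0.503), the let-7 family 1 rise and 3 adjusted over the list alone (0.239), the Mir17hg clusters 1 rise (0.503), the hepatocyte list 1 rise (0.251) and the myeloid list 1 fall (0.635). The remaining lists had 0 calls, and camera adjusted p of lists that did not pass ran from 0.138 to 0.967.

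In cells given RAW saline EVs, miR-146a-5p rose from 17565 ± 622 to 31090 ± 1405 CPM, and miR-155-5p rose 1.37-fold, from 1038 ± 112 to 1424 ± 43.0 CPM (edgeR's test, adjusted p = 2.40e-11 and 1.00e-04). miR-155-3p, from the other arm of that hairpin, fell from 177 ± 43.3 to 65.6 ± 11.4 CPM (adjusted p = 2.17e-05). let-7c-1-3p fell 4.01-fold, to 46.4 ± 7.02 CPM, and miR-27a-5p from 341 ± 22.7 to 128 ± 15.0 CPM (both adjusted p = 2.34e-08). miR-3473a rose 4.02-fold, from 16.3 ± 12.0 to 74.0 ± 19.9 CPM (adjusted p = 4.31e-04). Other rises, in log2, were those of miR-5099 (0.63), miR-3535 (0.58), miR-7a-5p (0.56), miR-7b-5p (0.55) and miR-23a-3p (0.41). Other falls were those of miR-30b-3p (−1.15), miR-16-1-3p (−1.14), miR-27b-5p (−0.97), miR-221-5p (−0.55), miR-130b-5p (−0.54) and miR-328-3p (−0.49). All of these were beyond every PBS library in 3 of 3 libraries and kept their calls without any 1 library. In total 32 miRNAs passed, 17 higher and 15 lower, 2 and 6 of them by at least 2-fold, and the groups did not overlap for 72, or 31.4%. The split was 10 and 32 with upper-quartile scaling, 9 and 42 with library size alone, 12 and 21 with the authors' scaling, 11 and 23 with limma-trend, and 20 and 11 with DESeq2.

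In cells given RAW saline EVs, 19 of the 32 calls held without any 1 library. The other calls ended in at least 1 such fit, at log2 changes of the same sign that were 0.583 to 1.10 times the full value. The rise of miR-503-5p (0.65) ended without RAW saline EV library 3 (edgeR, adjusted p = 0.123). That of miR-194-5p (0.50, higher in 2 of 3 libraries) ended without PBS library 1 (0.118), PBS library 2 (0.102) or RAW saline EV library 3 (0.292). The rise of miR-351-5p (0.33) ended without the same 3 libraries (up to 0.195) and that of miR-16-5p (0.25) without PBS library 1 or RAW saline EV library 3 (up to 0.163). The fall of miR-92a-1-5p (−1.42) ended without PBS library 1 (0.0547), RAW saline EV library 1 (0.0607) or RAW saline EV library 3 (0.0625), and that of miR-222-5p (−0.84) without PBS library 1 (0.0687), RAW saline EV library 2 (0.0512) or RAW saline EV library 3 (0.0916). miR-3968 (−0.48) lost its call without PBS libraries 2 or 3 or RAW saline EV libraries 1 or 3 (up to 0.103). miR-148a-3p (1.38) lost it without any library but PBS library 2 (up to 0.200), miR-378b (0.45) without any but RAW saline EV library 2 (up to 0.131) and miR-18a-5p (−0.35) without any but PBS library 1 (up to 0.103). In those fits the log2 changes were 1.04 to 1.52, 0.40 to 0.49 and −0.34 to −0.32. miR-122-5p had 29 reads against 17 (0.86, adjusted p = 0.202) and miR-21a-5p stood at 0.16 (0.0566), miR-142a-3p at 0.02 (0.889), miR-126a-3p at −0.22 (0.153), miR-223-3p at −0.36 (0.631) and miR-451a at 1 read against 0. None of the 12 lists passed (0 by camera, adjusted p = 0.295 to 0.918, also 0 at an unadjusted p under 0.05). By fry 2 passed, but fry asks only whether a list's members changed in 1 direction, without comparing them with other miRNAs. Inflammation-induced miRNAs had 2 rises and 1 fall (3 and 1 adjusted over the list alone), the miR-221 and miR-222 cluster 2 falls (2), the hepatocyte list 1 rise, the miR-23/27/24 clusters 1 rise and 1 fall (3 and 1), the Mir17hg clusters 1 fall and miR-15/16 1 rise. The signs of test, median and mean differed for 5 of 12 lists: inflammation-induced, Mir17hg, miR-30, miR-29 and miR-23/27/24.

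Cells given RAW Con A EVs and RAW saline EVs differ in whether the EV-producing cells had received Con A. How many EV preparations each group received is not known here, so this cannot be told apart from differences between preparations. Between these groups miR-27a-5p was higher with RAW Con A EVs at 246 ± 26.9 against 128 ± 15.0 CPM (0.88, SE 0.17, edgeR's test, adjusted p = 0.00198), in 3 of 3 libraries, and kept its call without any 1 library. let-7c-1-3p was higher by 1.24 (SE 0.26, adjusted p = 0.00378) and lost its call without RAW Con A EV library 3 (1.03, adjusted p = 0.113). miR-503-5p, at 250 ± 12.8 against 418 ± 127 CPM (−0.71, adjusted p = 0.0157), miR-155-5p (−0.35, adjusted p = 0.0143) and miR-351-5p (−0.40, adjusted p = 0.0227) were lower, and lost their calls without RAW Con A EV library 3 or RAW saline EV library 3. Without the former they stood at −0.73, −0.39 and −0.34 (adjusted p = 0.113, 0.0508 and 0.206), and without the latter at −0.45, −0.32 and −0.29 (0.223, 0.0904 and 0.220). miR-22-3p (−0.33) was not called without these or RAW saline EV library 2 (up to 0.383), miR-142a-3p (−0.25) without these 3 or RAW Con A EV library 2 (up to 0.258) and miR-130b-5p (0.37) without any library but RAW Con A EV library 1 (up to 0.214). In all fits that ended a call the log2 changes kept their sign, at 0.632 to 1.12 times the full value. So 8 passed, 3 higher and 5 lower, and without RAW Con A EV library 3 it was 1, without RAW saline EV library 3 it was 2 and without RAW saline EV library 2 it was 5. Groups did not overlap for 37 miRNAs, or 16.2%, beside 10% by chance, and 33 miRNAs had an unadjusted p under 0.05. The split was 3 and 1 with upper-quartile scaling and 3 and 3 with the authors' scaling. miR-146a-5p stood at 0.10 (adjusted p = 0.509), miR-122-5p at 0.97 (0.154), miR-21a-5p at 0.02 (0.888), miR-126a-3p at 0.28 (0.183), miR-223-3p at −0.30 (0.871) and miR-451a at 6 reads against 1. None of the 12 lists passed (0 by camera, adjusted p = 0.198 to 0.942, with 2 at an unadjusted p under 0.05 and 0 by fry). Adjusted over the list alone, miR-222-3p (−0.27) in its cluster, 1 hepatocyte miRNA, and miR-155-3p (0.72) and miR-155-5p among inflammation-induced miRNAs had calls. Signs of test, median and mean differed for let-7, miR-30, miR-23/27/24 and hepatocyte miRNAs (4 of 12).

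Compared directly with RAW Con A EVs, serum Con A EVs left miR-155-5p at 217 ± 13.8 against 1121 ± 40.4 CPM, 5.14-fold lower, and miR-146a-5p at 18942 ± 826 against 33261 ± 4185 CPM (edgeR's test, adjusted p = 7.99e-19 and 1.17e-11). miR-192-5p, miR-194-5p and miR-155-3p were lower, with log2 differences of −2.05, −2.07 and −1.42. Of the 8 tested cluster members on chromosome X, 6 were lower, with miR-450b-5p at −1.95, miR-450a-5p at −1.46, miR-542-3p at −1.19, miR-503-5p at −1.16 and miR-322-3p at −1.12. miR-7a-5p (−0.83), miR-7b-5p (−0.78), miR-221-3p (−0.56), miR-222-3p (−0.51), miR-23a-3p (−0.50), miR-21a-5p (−0.37) and miR-3473a (−1.96) were lower too. Higher with serum Con A EVs were miR-451a (3.04, 67 against 6 reads), miR-148a-3p (2.27), miR-92a-1-5p (1.97), miR-122-5p (1.44), miR-181a-2-3p (1.14), miR-16-1-3p (0.93), miR-27a-5p (0.58), miR-106b-3p (0.40), miR-9-5p (0.32) and miR-126a-3p (0.32). These miRNAs had adjusted p from 7.99e-19 to 0.00961, did not overlap between the groups (3 of 3 libraries) and kept their calls without any 1 library. In total 80 miRNAs passed, 41 higher and 39 lower, 8 and 10 of them by at least 2-fold, with 107 (46.7%) not overlapping. The split was 85 and 19 with library size alone, 22 and 33 with DESeq2, and 25 and 38 with limma-trend.

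Between cells given serum Con A EVs and RAW Con A EVs, 47 of the 80 calls held without any 1 library. Fits without single libraries left 56 to 76 calls in place of 80. Calls that ended had log2 changes of the same sign, at 0.553 to 1.16 times the full value. miR-5114 (1.64), miR-125b-5p and let-7e-5p ended without RAW Con A EV library 3 (edgeR, adjusted p = 0.0832, 0.0546 and 0.116). let-7f-1-3p (0.99) ended without RAW Con A EV library 2 or serum Con A EV library 1 (up to 0.0588), and miR-30a-5p without RAW Con A EV library 1 or serum Con A EV library 1 (up to 0.0600). miR-338-5p (0.87) ended without RAW Con A EV libraries 2 or 3 or serum Con A EV library 3 (up to 0.268), miR-877-3p (1.02) without RAW Con A EV libraries 2 or 3 or serum Con A EV library 2 (up to 0.172) and miR-16-2-3p (0.91) without RAW Con A EV library 3 or serum Con A EV libraries 1 or 2 (up to 0.115). miR-142a-3p (0.19), miR-18a-5p and miR-19b-3p ended without RAW Con A EV libraries 2 or 3 or serum Con A EV libraries 2 or 3 (up to 0.214, 0.0936 and 0.157). miR-22-5p (−0.89, lower in 2 of 3 libraries) ended without RAW Con A EV libraries 2 or 3 or serum Con A EV libraries 1 or 2 (up to 0.168), and miR-23b-5p (1.12) without any library but serum Con A EV library 3 (up to 0.111). miR-223-3p stood at 0.67 (adjusted p = 0.323). Inflammation-induced miRNAs were lower as a list (median −0.37, camera adjusted p = 0.0021, and adjusted p = 0.0525 with an estimated correlation), with 1 member higher and 4 lower, the same adjusted over the list alone. Of the miR-23/27/24 clusters 1 was higher and 4 lower (camera adjusted p = 0.319), of the hepatocyte list 1 and 2 (0.0667), of the Mir17hg clusters 2 and 1 (0.319) and of the myeloid list 1 and 0 (0.697). Of the miR-221 and miR-222 cluster 2 were lower (0.268), of let-7 2 (0.528), of the miR-99b cluster and relatives 2 (0.697) and of miR-30 1 (0.914). The other lists had 0 calls. Over the 60 list tests of the 5 comparisons 4 passed with the preset correlation and 1, the miR-221 and miR-222 cluster with serum Con A EVs against PBS, with an estimated correlation.

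**Figure D2:**
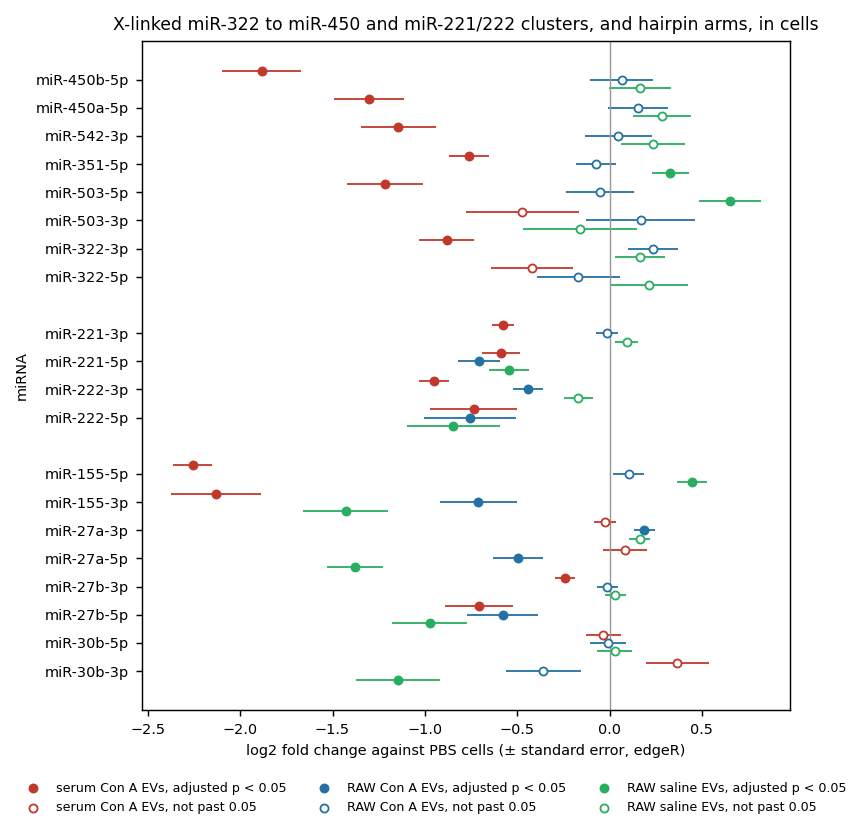
log2 fold change against PBS cells (points, bars ± SE) of the chromosome X cluster from miR-322 to miR-450, the miR-221 and miR-222 cluster and both arms of 4 hairpins in cells given serum Con A, RAW Con A or RAW saline EVs, with filled points past an adjusted p of 0.05. miR-155-5p and miR-155-3p lie at −2.26 and −2.13 with serum Con A EVs and on opposite sides of 0, at 0.45 and −1.43, with RAW saline EVs.

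Against the shared PBS libraries, miR-155-3p, miR-221-5p, miR-222-5p and miR-27b-5p fell and miR-148a-3p rose in all 3 groups given EVs. miR-221-5p kept its call in each group without any 1 library. The others lost theirs in at least 1 group without single PBS, serum Con A EV, RAW Con A EV or RAW saline EV libraries, at adjusted p (edgeR) of up to 0.222 for miR-155-3p, 0.195 for miR-222-5p, 0.240 for miR-27b-5p and 0.200 for miR-148a-3p. Across 229 miRNAs, which are not independent replicates, log2 changes with RAW Con A and RAW saline EVs had r = 0.710 and rho = 0.692, beside a simulated r of 0.488 (0.271 to 0.688) with no effect, and a covariance of 0.152 beside 0.0260 simulated. With a filter of 10 CPM in 3 libraries r was 0.649, within its simulated range of 0.157 to 0.730, and the covariance 0.287 beside 0.0862 (up to 0.197). Both sets called 7 miRNAs higher and 9 lower, where independent lists would share 1.04 and 0.786, with 0 called in opposite directions. Serum Con A and RAW Con A EVs had r = 0.598 and rho = 0.133 (simulated r 0.504, 0.325 to 0.695, covariance 0.207 beside 0.0249), with 3 and 5 shared calls where independent lists give 1.10 and 1.62, and 4 opposite. Serum Con A and RAW saline EVs had r = 0.261 and rho = −0.04 (simulated r 0.507, 0.304 to 0.683, covariance 0.0932 beside 0.0254), with 1 and 5 shared calls where independent lists give 1.34 and 2.03, and 10 opposite. miR-451a, with 0 reads in PBS cells, had log2 changes of 7.28, 4.23 and 1.94 with serum Con A, RAW Con A and RAW saline EVs. Such large changes of few miRNAs weigh heavily on r and covariance and little on rho. For serum Con A EVs, with rho of 0.133 and −0.04, r and covariance thus do not show a broad shared response. The 3 PBS libraries cannot be split, so part of any excess may come from the shared controls.

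The EVs were compared by ratio of CPM, each ratio setting 1 library against 1 other and not condition against condition, as there were no replicates. In serum EVs, miR-148a-3p took 12.0% of miRNA reads after saline (95% Wilson interval 11.8 to 12.2%) and 42.6% after Con A (42.4 to 42.8%). The hepatocyte miR-122-5p took 9.95% (9.79 to 10.1%) and 39.2% (39.0 to 39.4%). Their ratios, with the 95% counting interval, were 3.55 (3.49 to 3.61) and 3.94 (3.87 to 4.01). Other miRNAs at higher CPM after Con A were miR-5099 (2.57), miR-22-3p (2.53, 2.27 to 2.83), miR-192-5p (2.00, 1.91 to 2.09), miR-194-5p (1.66, 1.39 to 2.00), miR-146a-5p (1.25, 1.15 to 1.37) and miR-6538 (12.5, 3.31 to 105, from 63 reads against 2). These 8 were the ones with an interval above 1 among 124 miRNAs considered, and 110 had an interval below 1, at a median log2 ratio of −2.35. At least 4-fold apart were 75, of which 1 was higher and 74 lower. By TMM 48 had an interval above 1 and 59 below, and by the authors' normalized values 122 and 0. The authors' serum values are reads divided by 126 (saline) and 2 (Con A). What these numbers count is not stated. A plant miRNA was added to the EV lysates as a spike-in, and if the divisors are its reads, the authors' values are scaled to the spike-in. Taken as counts, their ratio of 63 has an interval of 17.1 to 526. Of the 110 miRNAs lower by CPM, 109 were higher by the authors' values, while the 8 higher by CPM were higher by each scaling.

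Among the many miRNAs at lower CPM in serum EVs after Con A, miR-215-5p was 69.9-fold lower (57.4 to 86.1), the islet miR-375-3p 66.5-fold (39.1 to 123), miR-574-3p 43.6-fold, miR-142a-3p 39.4-fold, the epithelial miR-200a-3p and miR-200b-3p 36.3-fold and 31.2-fold and the muscle miR-206-3p 25.6-fold. The stromal miR-199a-3p and miR-199b-3p, whose mature sequences are identical, were 43.3-fold and 38.2-fold lower. The epithelial miR-205-5p had 1 read against 167 (ratio 0.00237, 5.96e-05 to 0.0134) and miR-144-5p, from the erythroid cluster of miR-451a, 3 against 49 (0.0242, 0.00482 to 0.0750). miR-486a-3p was 33.3-fold lower, miR-451a 7.17-fold, miR-25-3p 8.02-fold, miR-99a-5p 6.02-fold, and miR-486a-5p and miR-486b-5p, which have identical mature sequences, 5.05-fold and 5.07-fold. let-7i-5p was 13.2-fold lower, miR-21a-5p 9.26-fold, miR-126a-3p 4.50-fold, miR-30d-5p 3.32-fold and miR-223-3p 2.09-fold. By the authors' values all of these are higher after Con A, apart from miR-205-5p, and by TMM miR-126a-3p, miR-30d-5p and miR-223-3p are too. Least reduced among miRNAs with an interval below 1 were miR-148b-3p (0.697), miR-1198-5p (0.652), miR-185-5p (0.626) and miR-28a-3p (0.599), all above 1 by TMM. Against 10000 abundance-matched random lists, the median ratio of 3 hepatocyte miRNAs, 2.00, lay at percentile 100. The medians of 5 epithelial and islet miRNAs, 36.3-fold lower, 6 erythrocyte miRNAs, 12.1-fold lower, and 3 stromal miRNAs, 38.2-fold lower, lay at percentiles 0.535, 3.40 and 3.34. Of these 4 lists those of hepatocyte and of epithelial and islet miRNAs lay outside the range of 95% of matched lists, and those of erythrocyte and stromal miRNAs within it. The miR-23/27/24, Mir17hg, miR-181 and miR-30 lists lay at 6.50, 8.26, 12.4 and 21.1, the miR-99b list at 38.9, and the let-7, inflammation-induced and myeloid lists at 80.9, 87.5 and 88.4.

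**Figure D3:**
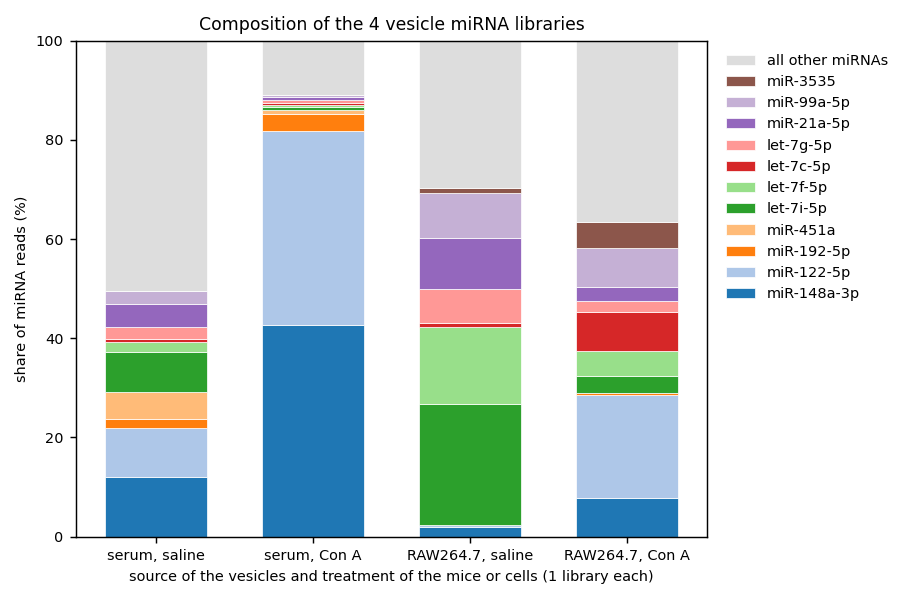
Share of miRNA reads (%, stacked bars from 0) of 11 miRNAs in the 4 EV libraries, 1 library per bar. miR-122-5p and miR-148a-3p together take 21.96% of serum saline reads and 81.8% of serum Con A reads.

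In RAW EVs, miR-122-5p took 0.353% of miRNA reads with saline (0.320 to 0.389%) and 20.8% with Con A (20.6 to 21.02%), a ratio of 59.0 (53.5 to 65.2). miR-148a-3p took 1.91% (1.83 to 1.99%) and 7.71% (7.57 to 7.85%). miR-155-5p was 5.90-fold higher with Con A (3.35 to 11.2, 97 against 14 reads) and miR-146a-5p 1.45-fold (1.33 to 1.57). Also higher were miR-5099 (34.0), the epithelial miR-184-3p (20.9), let-7c-5p (10.1, 9.41 to 10.8), miR-412-5p (7.54), miR-320-3p (7.25), miR-493-5p (6.67), let-7b-5p (6.27), miR-192-5p (5.71), miR-183-5p (5.60), miR-3535 (4.80) and miR-378a-3p (1.85). let-7i-5p, the most abundant miRNA with saline at 242571 CPM, was 7.03-fold lower with Con A (6.81 to 7.25). miR-21a-5p was 3.74-fold lower (3.60 to 3.88), let-7g-5p 3.26-fold, let-7f-5p 3.10-fold, miR-99b-5p and miR-99b-3p 6.51-fold and 6.15-fold, and miR-130b-5p 22.3-fold. The passenger strands miR-25-5p, miR-30b-3p, miR-30c-2-3p and miR-27a-5p were 33.5-fold, 24.7-fold, 10.9-fold and 5.70-fold lower. let-7 members differ by few bases and may share reads. miR-365-2-5p had 2 reads against 281 (ratio 0.00606, 7.30e-04 to 0.0221), miR-139-3p 2 against 119 (0.0143, 0.00171 to 0.0528) and miR-128-1-5p 0 against 73, at least 28.6-fold lower with a floor of 3 reads. Blood cell miRNAs miR-142a-3p and miR-451a were 3.72-fold and 1.75-fold lower, and miR-690 13.8-fold. Of 134 miRNAs considered, 51 had an interval above 1 and 52 below, and the TMM counts were 55 and 51. At least 4-fold apart were 30, with 14 higher and 16 lower. Against matched lists the miR-23/27/24 clusters lay at percentile 98.96 (median ratio 2.38, 6 miRNAs) and the Dlk1-Dio3 imprinted cluster at 95.9 (1.88, 5 miRNAs). The stromal list lay at 71.5, miR-30 at 41.5, miR-221 and miR-222 at 39.5, inflammation-induced miRNAs at 35.5, let-7 at 27.2, Mir17hg at 26.0, erythrocyte miRNAs at 17.2 and the miR-99b list at 17.0.

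Between the EVs of Con A-injected mice and of Con A-treated RAW264.7 cells, erythrocyte and liver miRNAs stood at higher CPM in serum. miR-451a was 14.3-fold higher (11.3 to 18.3), miR-486a-5p and miR-486b-5p 10.97-fold and 10.4-fold, miR-192-5p 9.83-fold, miR-22-3p 8.51-fold, miR-194-5p 8.21-fold, miR-203-3p 7.46-fold, miR-148a-3p 5.53-fold and miR-122-5p 1.88-fold (1.86 to 1.91). The granulocyte miR-223-3p was 4.92-fold higher, the lymphocyte miR-150-5p 3.92-fold, miR-223-5p had 103 reads against 2 (ratio 20.8, 5.61 to 174) and miR-6538 63 against 1 (25.4, 4.40 to 1020). At lower CPM in serum were miR-3535, 460.1-fold (335 to 651), miR-5099, 123-fold, the imprinted miR-127-3p, 76.8-fold, miR-221-3p, 53.3-fold, let-7c-5p, 26.0-fold, and miR-99a-5p, 19.2-fold. let-7f-5p, miR-378a-3p, miR-155-5p, let-7i-5p and miR-21a-5p were 9.59-fold, 8.10-fold, 6.16-fold, 5.69-fold and 5.37-fold lower. miR-146a-5p, miR-30d-5p and miR-126a-3p were 1.72-fold, 1.83-fold and 1.38-fold lower but higher by TMM. miR-184-3p had 0 reads against 368, at least 304-fold lower, and miR-9-5p 0 against 91, at least 75.2-fold. Of 120 miRNAs considered 72 were at least 4-fold apart, 11 higher and 61 lower. In all 18 had an interval above 1 and 94 below (median log2 ratio −2.05), and by TMM 44 and 57. Percentiles against matched lists were 100 for hepatocyte, 99.2 for erythrocyte and 98.6 for myeloid miRNAs, with 3 members each. The erythrocyte members were miR-451a and the identical miR-486a-5p and miR-486b-5p. The myeloid members were both arms of the miR-223 hairpin and miR-142a-5p (ratio 1.21, 0.781 to 1.93). Such members are not independent, so the erythrocyte and myeloid percentiles may overstate how unusual these lists are. The other percentiles were 77.5 for miR-30, 59.0 for miR-23/27/24, 43.7 for inflammation-induced miRNAs, 27.7 for Mir17hg, 13.9 for the miR-99b list, 7.04 for let-7, 6.63 for stromal miRNAs and 0.270 for the Dlk1-Dio3 cluster.

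Lists too sparse for these tests are given as summed CPM in serum saline, serum Con A, RAW saline and RAW Con A EVs, in that order. Lymphocyte miRNAs summed to 6864, 933, 749 and 830 CPM and endothelial and platelet miRNAs to 14372, 3138, 3493 and 4337. Muscle miRNAs reached 2437, 159, 192 and 334, the imprinted placental and embryonic Sfmbt2 cluster 174, 83.8, 0 and 22.2, and miR-29 members 5237, 2588, 1803 and 2083. The miR-15/16 list stood at 1143, 227, 697 and 578 and miR-181 at 5109, 637, 1072 and 1690. These serum sums, all lower after Con A by CPM, are all higher by the authors' scaling, and by TMM those of Sfmbt2 and miR-29 are, at log2 ratios of 1.14 and 1.18. In the cells, muscle, Sfmbt2 and Dlk1-Dio3 miRNAs had 0 members at a testable level, erythrocyte and lymphocyte lists 1 each, and the miR-181, epithelial and endothelial lists 2 each.

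The last comparison asked whether the miRNAs abundant in a given EV preparation were higher in cells that received it. The 30 most abundant miRNAs of RAW Con A EVs, among them miR-146a-5p, miR-7a-5p and miR-122-5p, were higher as a list, with TMM, in cells given those EVs, with 9 rising and 0 falling (10 and 0 adjusted over the list alone) and a median log2 change of 0.09 (camera adjusted p = 3.85e-06, and adjusted p = 0.00551 with an estimated correlation). Those of RAW saline EVs were higher with TMM in cells given RAW saline EVs, with 6 and 0 (9 and 1 adjusted over the list alone), a median of 0.05 and adjusted p = 0.00147 (and 0.0343 with an estimated correlation). Those of serum Con A EVs had 5 rises and 6 falls in cells given serum Con A EVs (5 and 7 adjusted over the list alone), a median of −0.02 and camera adjusted p = 0.928, up by camera and down by fry. Of the 9 rises of the RAW Con A list in cells given RAW Con A EVs, several ended in at least 1 fit without a single library. They were those of miR-148a-3p, let-7f-5p, miR-3535, miR-5099, miR-21a-5p and miR-27a-3p. The list medians depend on the scaling. With library size alone that of the RAW Con A list in cells given RAW Con A EVs was −0.05, with 5 rises and 4 falls (camera adjusted p = 0.0256, still up against other miRNAs), and with upper-quartile scaling 0.05, with 7 and 0 (6.49e-05). That of the RAW saline list in cells given RAW saline EVs was −0.07 with library size alone, with 4 rises and 6 falls (0.0855), and −0.04 with upper-quartile scaling, with 4 and 3 (0.0358). The lists share 18 to 22 of 30 miRNAs, and lists from the other EVs passed as well. In cells given RAW Con A EVs the serum Con A list had adjusted p = 1.45e-04 (0.00996 with an estimated correlation) and the RAW saline list 8.21e-05 (0.0151). In cells given RAW saline EVs the serum Con A list had 0.00211 (0.0237) and the RAW Con A list 9.15e-05 (0.0106). Of the 8 miRNAs at least 8 times higher in CPM in serum Con A EVs than in either RAW EV library, 4 were tested. Some stood higher still in serum saline EVs, as miR-451a did at 54704 against 7631 CPM. In cells given serum Con A EVs miR-451a rose and miR-192-5p, miR-194-5p and miR-22-3p fell (median −1.31, camera adjusted p = 0.0102, and adjusted p = 0.0785 with an estimated correlation). In cells given RAW Con A or RAW saline EVs this list of 4 had adjusted p of 0.429 and 0.0540. miR-486a-5p and miR-486b-5p, not tested, had 17 and 19 reads against 0 in PBS cells after serum Con A EVs, at least 5.19-fold and 5.80-fold higher.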

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

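All tests of explanations in this part were chosen only after the result was seen, and the differences between groups come from the planned model.

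Some miRNAs moved apart between cells given serum Con A EVs and cells given RAW EVs, by edgeR's test of the difference itself. Against RAW Con A EVs the log2 difference was −0.83 for miR-7a-5p, −0.78 for miR-7b-5p, −0.37 for miR-21a-5p (SE 0.06) and 0.66 for miR-339-5p, each higher in one group than PBS and lower in the other. Against RAW saline EVs it was −2.71 for miR-155-5p, −2.41 for miR-194-5p, −1.87 for miR-503-5p, −1.09 for miR-351-5p, −0.99 for miR-22-3p, −0.86 for miR-7a-5p, −0.80 for miR-7b-5p, 0.74 for miR-339-5p, 1.04 for miR-130b-5p and 2.32 for miR-92a-1-5p (SE 0.35). Adjusted p of these differences ran from 3.42e-21 to 6.98e-06. The miRNAs were picked because the same libraries called them higher than PBS in 1 group and lower in the other. Small p of the differences were therefore nearly given in advance and add no support. Some single effects against PBS among them were not called when 1 library was left out (edgeR). For miR-21a-5p this held for 3 libraries with serum Con A EVs (adjusted p up to 0.154) and for 5 with RAW Con A EVs (up to 0.140). It held for 5 libraries for miR-339-5p with RAW Con A EVs (up to 0.130) and for 1 with RAW saline EVs (0.0607), and for 2 for miR-7b-5p with serum Con A EVs (up to 0.0855). For miR-92a-1-5p it held for 2 with serum Con A EVs (up to 0.135) and for 3 with RAW saline EVs (up to 0.0625). With RAW saline EVs it also held for 3 libraries for miR-194-5p (up to 0.292) and miR-351-5p (up to 0.195), 4 for miR-22-3p (up to 0.109) and 1 for miR-503-5p (0.123). In the EVs, miR-320-3p stood at a Con A over saline ratio of 7.25 (5.81 to 9.15) in RAW EVs and 0.159 (0.135 to 0.188) in serum EVs, a difference that was not tested. The median serum ratio of the miRNAs considered was 0.196 by CPM. The serum direction depends on the scaling. The log2 ratio of miR-320-3p, −2.65 by CPM, stays below 0 by TMM, a shift of 2.19. By the authors' values, a shift of 7.32, it turns above 0, as in RAW EVs.

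miR-122-5p and miR-148a-3p, which are abundant in liver and in serum, stood high in RAW Con A EVs, although these came from a macrophage line in EV-free medium. Carry-over from the serum Con A EV preparation would bring its other abundant miRNAs in proportion to miR-122-5p. At most 0.261 of the excess this needs was seen (miR-148a-3p), with 0.16 for miR-192-5p, −0.06 for miR-486a-5p and −0.10 for miR-451a, which argues against carry-over as the whole source. A share of reads from the medium stays open. The ratio of miR-122-5p between the 2 RAW EV libraries was 59.0, but it was singled out for this ratio, and miRNA names do not tell bovine from mouse sequences. Release by RAW264.7 cells after Con A stays open and may account for it, but the EV level was 10198 times that in PBS cells given Con A, and with 1 library per condition it cannot be told apart from a difference between the 2 preparations.

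miR-122-5p, miR-148a-3p and miR-451a rose in cells given serum Con A EVs. Reads misassigned to all cell libraries would raise the other groups alike. The highest level in another group was 0.317 of that in these cells, but the 3 miRNAs were singled out as higher there, so this decides nothing. Vesicle RNA of the sequenced composition may explain miR-148a-3p beside miR-122-5p, since the added level over the vesicle level differed 1.36-fold (1.11 to 1.69). This is below a bound of 3 set after the values were seen, though the interval excludes equal quotients. For miR-451a this quotient was 19.8 times that of miR-122-5p (14.6 to 26.4). It argues against that composition for miR-451a only if cells take up and lose these miRNAs alike, which was not tested. For miR-486a-5p, with 17 reads, the quotient was 4.22 times that of miR-122-5p (2.29 to 6.598). The interval excludes equal quotients but holds the bound of 3, so by that bound it decides nothing. These intervals cover the counting error of pooled reads only. Transcription in the recipient cells stays open, since the other strands, miR-122-3p and miR-148a-5p, had 0 reads where the vesicles would bring 0.0103 and 0.0192. miR-192-5p, which would gain 22.7 CPM at the rate of miR-148a-3p, changed by −715 CPM (both from pooled reads without TMM scaling).

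miRNAs abundant in RAW EVs were higher with TMM in cells given those EVs, while with library size alone their median log2 changes were negative (−0.05 with RAW Con A EVs, −0.07 with RAW saline EVs). If abundant miRNAs as a class read higher in these libraries, matched lists would move alike. The RAW Con A list lay at percentile 98.4 of 10000 abundance-matched lists. This cannot decide against abundance alone, since the RAW saline list reached 99.2 in cells given serum Con A EVs. That list did not pass there, with 3 rises, 7 falls and camera adjusted p = 0.928. In cells given RAW saline EVs the RAW saline list lay at 94.3, which leaves abundance open there. These percentiles do not single out the EVs given, since other lists stood at similar ones: the RAW saline list at 99.4 and the serum Con A list at 92.4 in cells given RAW Con A EVs, and the serum Con A and RAW Con A lists at 99.4 and 99.3 in cells given RAW saline EVs. Whether the vesicles given matter, and not miRNAs common to all vesicles, cannot be told apart, since the 7 miRNAs of the serum list outside the RAW Con A list had a median log2 change of 0.0626 beside 0.0873 for the RAW Con A list.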

How the results depend on the processing

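Tests with the authors' scaling in edgeR, other scalings of the EV lists in cells and EV totals without miR-148a-3p and miR-122-5p were chosen only after the data were seen. Named calls that held in every alternative numbered 25 of 36 for serum Con A EVs against PBS, 7 of 26 for RAW Con A EVs against PBS, 17 of 26 for RAW saline EVs against PBS, 1 of 8 for RAW Con A against RAW saline EVs and 26 of 42 for serum Con A against RAW Con A EVs. The number of calls ran from 35 to 49, 11 to 18, 22 to 36, 1 to 11 and 56 to 76 when each library was left out, in that order, where fewer samples lower the power. RAW Con A EVs against PBS had 16 calls with no filter, where more miRNAs are tested, and RAW saline EVs against PBS 51 with library size alone. RAW Con A against RAW saline EVs had 4 calls with upper-quartile scaling, 5 with library size alone, 4 with DESeq2, 4 with limma-trend and 5 with 2 groups alone. Between serum Con A and RAW Con A EVs library size alone gave positive log2 values for miR-19b-3p (0.0189), miR-30a-5p (0.0276) and miR-30d-5p (0.17). Of 60 list tests 1 passed with an estimated correlation and 14 with fry. Of 12 tests of EV lists in cells 7 passed with TMM, 7 with DESeq2 size factors, 8 with upper-quartile scaling and 3 with library size alone, where list medians in cells given RAW EVs also turned negative for all lists of 30. The correlation of serum Con A with RAW Con A EV responses was 0.459 and with RAW saline EV responses 0.391 with 10 CPM in 3 libraries. That of RAW Con A with RAW saline EV responses was 0.649, within the simulated 0.157 to 0.730, where the 0.710 of the default filter lay above 0.688. Apart from these fits to fewer samples or more miRNAs, the cause was not tested.

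As a hint only, a replicate block from the sample numbers gave 50, 23, 34, 9 and 81 calls. 1 of 12 libraries correlated best with its own number, and 2 of 18 same-number pairs had r above 0.1 (−0.30 to 0.16), so the numbers do not show pairing. The block moved inflammation-induced miRNAs in serum Con A EVs against PBS to adjusted p = 0.0579 (camera), beside 0.0390 with library size alone and 0.123 with an estimated correlation.

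In serum EVs 75 miRNAs were at least 4-fold apart by CPM, and 28 were by TMM, 28 without miR-148a-3p and miR-122-5p in the totals, 118 by the authors' values and 44 with at least 200 reads. The log2 ratio turned positive by TMM, without the 2 miRNAs and by the authors' values for miR-148b-3p (1.67, 1.58, 6.80), miR-1198-5p (1.58, 1.48, 6.70), miR-185-5p (1.52, 1.43, 6.64), miR-28a-3p (1.45, 1.36, 6.58), miR-223-3p (1.13, 1.03, 6.25) and miR-30d-5p (0.46, 0.37, 5.58), and by TMM and the authors' values for miR-126a-3p (0.0228, 5.15). By the authors' values alone it turned positive for miR-215-5p (1.19), miR-375-3p (1.26), miR-574-3p (1.87), miR-199a-3p (1.88), miR-144-5p (1.95), miR-142a-3p (2.02), miR-199b-3p (2.06), miR-200a-3p (2.14), miR-486a-3p (2.26), miR-200b-3p (2.35), miR-206-3p (2.64), let-7i-5p (3.60), miR-21a-5p (4.11), miR-25-3p (4.31), miR-451a (4.47), miR-99a-5p (4.73), miR-486b-5p (4.97) and miR-486a-5p (4.98). Each of these settings moves all miRNAs of a library by 1 factor, which is what turns these signs, and which factor is right was not tested. In RAW EVs 16 were at least 4-fold apart with at least 200 reads, where fewer miRNAs are considered, and 71 were 2-fold apart, and without the 2 miRNAs in the totals miR-99a-5p and miR-30d-5p turned to 0.26 and 0.15. Between serum Con A and RAW Con A EVs 44 were 4-fold apart by TMM, 44 without the 2 miRNAs and 37 with at least 200 reads. There miR-146a-5p (1.08, 1.19), miR-126a-3p (1.40, 1.51) and miR-30d-5p (0.99, 1.10) turned positive by TMM and without the 2 miRNAs.

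Not run were a spike-in scaling of its own, as no spike-in entry is in the tables analysed (whether the authors' EV divisors are spike-in reads is not stated), the authors' EV values for serum against RAW EVs, which are in no single normalized table, and the authors' pair scaling for comparisons other than serum Con A or RAW Con A EVs against PBS. A count of 0 leaves levels of up to 7.44 to 17.2 CPM open in a single cell library and of up to 8.97 to 26.1 CPM in an EV library. Over the 3 PBS libraries together it leaves up to 3.60 CPM open.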

Other observations

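Except for the splits of the samples, the tests in this part were chosen only after the result was seen.

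Summed over fixed lists, let-7 miRNAs, which restrain proliferation, took 143745 CPM of serum saline EVs and 492286 CPM of RAW saline EVs, against 24398 and 227455 CPM after Con A. The RAW sum follows its most abundant members, such as let-7i-5p (7.03-fold lower), and is no fall of the whole family. Of 9 let-7 members in RAW EVs, 3 had an interval above 1, let-7c-5p at 10.1 among them, and 4 below, with a median ratio of 1.08. Erythrocyte miRNAs stood at 150935 and 25972 CPM in serum EVs and at 3519 and 2365 CPM in RAW EVs. Hepatocyte miRNAs stood at 117854 and 428209 CPM in serum EVs and at 4234 and 211752 CPM in RAW EVs, in both cases saline first. The miR-221 and miR-222 cluster took 1824 and 482 CPM in serum EVs and 10889 and 19142 CPM in RAW EVs. The serum directions depend on the scaling. The log2 ratio of Con A over saline was −2.56, −0.37 and 4.76 for let-7 by CPM, TMM and the authors' values, −2.54, −0.35 and 4.78 for erythrocyte miRNAs, 1.86, 4.05 and 9.18 for hepatocyte miRNAs and −1.92, 0.27 and 5.39 for miR-221 and miR-222.

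The most abundant miRNAs differed between EV libraries. After miR-148a-3p and miR-122-5p, serum saline EVs held let-7i-5p (79982 CPM), miR-451a (54704 CPM), miR-21a-5p (48097 CPM) and miR-25-3p (37592 CPM). RAW saline EVs held let-7i-5p, let-7f-5p (155605 CPM), miR-21a-5p (104398 CPM), miR-99a-5p (89728 CPM) and let-7g-5p (68333 CPM). RAW Con A EVs held miR-122-5p (208038 CPM), let-7c-5p (80024 CPM), miR-99a-5p (78571 CPM), miR-148a-3p (77074 CPM) and miR-3535 (52304 CPM). In serum Con A EVs miR-192-5p followed those 2, at 34258 CPM.

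Hairpins whose genes lie within 10 kb of each other may share their change. With mature miRNAs of 1 locus only and each pair of genes counted once, 49 pairs of neighbours in cells given serum Con A EVs differed by a mean of 0.339 log2 units where permuted positions gave 0.639 (1-sided permutation p = 0.0226, adjusted p = 0.0405 over 3 comparisons). With RAW Con A EVs it was 0.251 beside 0.419 (permutation p = 0.0270, adjusted p = 0.0405) and with RAW saline EVs 0.356 beside 0.482 (permutation p = 0.0771, adjusted p = 0.0771), which leaves it open there. A first count by miRNA name, with 93 pairs for 73 pairs of genes, had given permutation p = 9.20e-04, 0.0136 and 0.0151 in that order. The miR-322 to miR-450 cluster and the miR-221 and miR-222 cluster are among these pairs, and they were seen before this test.

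The rarer arm of a hairpin may fall where the commoner arm does not. In cells given RAW saline EVs the rarer arms of 57 hairpins had a median log2 change of −0.16, were below their commoner arm in 42 of 57 and had 0 rises and 6 falls, miR-155-3p, miR-27a-5p and miR-30b-3p among them (camera adjusted p = 0.00426, and adjusted p = 0.0190 with an estimated correlation). With RAW Con A EVs the median was −0.10, with 38 of 57 below and 0 rises and 5 falls (adjusted p = 0.0324, and 0.0436 with an estimated correlation), and with serum Con A EVs 0.02, with 27 of 57 below and 1 rise and 7 falls (0.938). Of the commoner arms 4 rose and 3 fell with RAW saline EVs, 2 and 3 with RAW Con A EVs, and 9 and 11 with serum Con A EVs. Between RAW Con A and RAW saline EVs the rarer arms had a median of 0.08, with 1 rise and 0 falls (camera adjusted p = 0.0844), and between serum Con A and RAW Con A EVs 0.11, with 7 and 4 (0.219). Among 10000 lists matched on abundance the medians lay at percentiles 5.34 with RAW saline EVs and 4.71 with RAW Con A EVs, which leaves open that rare miRNAs as a class read lower in these libraries. They lay at 61.4 with serum Con A EVs, 99.4 between RAW Con A and RAW saline EVs and 91.6 between serum Con A and RAW Con A EVs.

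Each cell comparison was refitted under the 10 splits of its 6 libraries into groups of 3, and in each comparison 1 split, the real one, gave as many calls. The real split gave 49 and the highest other 0 for serum Con A EVs against PBS, 26 and 0 for RAW Con A EVs against PBS, and 32 and 0 for RAW saline EVs against PBS. For RAW Con A against RAW saline EVs it gave 8 and the highest other 4, and for serum Con A against RAW Con A EVs 80 and 0. Splits this few, 10, cannot give a share under 0.05.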
